A study of Oryza sativa with 12 samples.

How the data were processed

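Total RNA of 12 rice libraries was measured by sequencing, 3 from each of 4 groups: the heat-sensitive line XN0437S and the heat-tolerant line XN0437T, each in control and with heat stress applied at night, sampled while grains were filling. Per the labels' protocols, ribosomal RNA was depleted with Ribo-Zero Gold, second strands were marked with dUTP, and paired reads of 150 bases were sequenced on an Illumina instrument. The temperature, the length of the stress and the organ sampled are not given in the sources used here. Small RNA and degradome data of the study are not analysed here.

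The deposited table gives whole-number counts per locus, named as counts in the file headers, made by the authors before deposit; per the submitters' processing notes the tools were cutadapt 1.9, HISAT2 2.2.1, StringTie 2.1.6, DESeq2 and edgeR, the last pair without versions. Values of the same loci are also deposited that the file headers name only as FPKM, which stands for fragments per kilobase scaled to library size. How either was computed, which tool did which step and whether loci were filtered are not given in the sources used here. The processing notes name the mouse build mm10, while the table uses rice MSU locus identifiers, so the build of the coordinates is not given in the sources used here. Coordinates are printed as the table gives them, and names come from the table's own annotation, from a reference table of rice genes and from the gene lists.

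The table held 50708 loci, of which 33205 were listed under an identifier from assembly and 17420 under an MSU identifier. A locus name was given for 45327 and missing for 5381, 693 carried several names and 11620 had no count in any library. Between 37.6% and 40.8% of the counts from 1 to 20 were multiples of 4, so a fragment may stand for several counts and low counts may be less precise than their size says. Most low counts were not multiples of 4, and how the counts were made is not given in the sources used here. No pair of replicates had matching values. Chi-square per degree of freedom between replicates of a group was 13.2 to 173, computed on counts divided by 4 at loci where the pair then summed to at least 20.

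Before the data were examined, the comparisons, tests, thresholds, gene lists and the naming rule were set. Counts were tested with edgeR 4.0.16 in R 4.3.3. Loci were kept by filterByExpr over the 4 groups, which left 33281, of which 28459 had a locus identifier, and 2627 identifiers were shared by more than 1 tested locus. Libraries were scaled by TMM factors, and a quasi-likelihood fit of the 4 group means (8 residual degrees of freedom) was tested with glmQLFTest. The 5 comparisons were stress against control in each line, the tolerant against the sensitive line in control and under stress, and the difference between the responses of the lines. All tests were two-sided. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes, without a minimum fold, and the count at 2-fold or more is given beside it. Log2 fold changes are fitted values with standard errors; levels are counts scaled to library size with TMM factors (CPM), as mean and SD of 3 libraries. Where a group was at 0 or a few counts, levels are given, and a fitted value only beside its counts and a value at the floor, with a floor of 12 counts per library where a bound was needed, taken as 3 fragments on the assumption of 4 counts for each.

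Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. Of 16 lists, 15 had at least 5 tested members; the list of organelle-encoded genes had no member in the table. The lists, with tested and listed members, were heat shock proteins (39 of 42), heat stress transcription factors (26 of 27), ER stress and protein folding (25 of 26), starch synthesis (30 of 30), endosperm storage proteins and their regulators (28 of 30), embryo and late maturation (26 of 27), alpha-amylases (8 of 9), photosynthesis (44 of 45), antioxidant enzymes (21 of 21), circadian clock (10 of 10), abscisic acid metabolism (8 of 8), conserved microRNA targets (53 of 55), microRNA machinery (26 of 27), cytosolic ribosomal proteins (148 of 151) and histones (14 of 14). HSP81-3, PUL and Amy3C had no locus in the table, and APX5 and TCP21 were left out because the annotation of their identifiers names another gene. Counts "adjusted over the list alone" use the same gene p-values with the adjustment over the members of that list. "With an estimated correlation" means camera with the correlation estimated from the residuals of each list. In that form camera also refers its statistic to the 8 residual degrees of freedom, which raises p-values by itself. The estimate for alpha-amylases, -0.064, was below the preset 0.01, yet their camera p between the lines in control rose from 3.72e-06 to 0.00138. A call lost this way is therefore not in itself a sign of correlation between members.

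The naming rule took, per comparison, the 5 largest rises and the 5 largest falls among called genes with an informative name, a mean of at least 10 CPM over the 12 libraries and no overlap between the 3 and 3 values, and in each list up to 3 members with the smallest adjusted p. For the difference between the lines only lists with a called member were used. A share of these genes is named in the text, together with members chosen after their values were seen, which are marked as such. Genes are named by symbol and MSU identifier.

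The procedure was tested on simulated counts drawn from the means and sizes of the real libraries, with 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold. A list of 30 other genes was raised 1.5-fold in each simulation and left out of the false calls. Its camera p was 1.15e-10 or less in every comparison. Of the genes changed 4-fold, 63.6% were recovered over all 33281 tested genes for stress in the sensitive line, 50.0% for stress in the tolerant line, 48.5% between the lines in control, 57.6% between the lines under stress and 45.5% for the difference between the lines. Among changed genes of at least 10 CPM the shares at 4-fold were 100.0%, 95.2%, 100.0%, 100.0% and 100.0%. At 2-fold the shares over all tested genes were 22.4%, 32.8%, 28.4%, 34.3% and 8.96%, and at 1.5-fold 10.4%, 5.97%, 1.49%, 5.97% and 0%. False calls numbered 4, 3, 3, 3 and 0. Of 100 lists with no change, 2, 6, 3, 2 and 2 had p under 0.05. Simulated genes were drawn independently of each other, so these lists do not test the preset correlation. Far fewer genes were changed than were called under stress in the real data. The first criterion, which set a minimum share recovered at 4-fold among all tested genes, was not met and was replaced by one among genes of at least 10 CPM.

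Alternatives set beforehand were DESeq2 1.42.0 (Wald test), median-of-ratios factors in edgeR, no low-count filter, a mean of at least 10 CPM, limma on log2 FPKM with a pseudocount of 1 or 0.1 (FPKM of at least 1 in 3 libraries), values summed over loci that share an identifier, only the groups compared, the replicate number as a block, leaving out each of the 12 libraries, a 2-fold minimum, an adjusted p under 0.01 and the estimated correlation. Scaling by library totals alone, counts divided by 4 and tests of gene ontology terms were added after seeing the data. Splits of the libraries against their labels were counted for each comparison.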

Results

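Ribosomal RNA-depleted total RNA of rice (Oryza sativa) was sequenced in a pair of near-isogenic lines, the heat-sensitive XN0437S and the heat-tolerant XN0437T, at the filling stage. Each line was sampled in control and under high night temperature stress, and each of the 4 groups of line and treatment had 3 libraries, 12 in all. The labels give the sampled material only as rice and name no organ. Nothing in the labels says that replicates came from separate plants, so the p-values measure only the spread between these libraries, which may be technical. Library totals ran from 85496090 to 100353570 counts, and 31536 to 33624 loci per library had a count. Between 37.6% and 40.8% of the counts from 1 to 20 were multiples of 4, so a fragment may stand for several counts and the depth in fragments may be lower than the totals. The 5 loci with the most counts, none with a named protein, took 33.3 ± 0.445% of the counts in the sensitive line in control, 27.3 ± 1.14% under stress, 25.9 ± 4.90% in the tolerant line in control and 26.01 ± 1.04% under stress (mean ± SD, n = 3). The first principal component, with 38.1% of the variance, separated stress from control in both lines. The second, with 8.61%, separated the lines mainly in control. There the sensitive line lay at 57.5 to 75.6 and the tolerant line at -86.4 to -56.2. Within tolerant control the order followed the share of the 5 loci: replicates 1 to 3 lay at -86.4, -72.3 and -56.2 with 21.7%, 24.6% and 31.3%. Sensitive control 1, with 32.8%, lay at 57.5. How far library composition enters the difference between the lines in control was not tested. Under stress the lines lay close together on the second component, at 5.07 to 12.6 and -12.1 to -3.38. On the first they lay apart under stress, at 95.3 to 100.1 in the sensitive and 114.0 to 116.9 in the tolerant line. Correlations between libraries, across genes, were 0.934 to 0.945 within groups and 0.877 to 0.939 between groups.

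**Figure D1:**
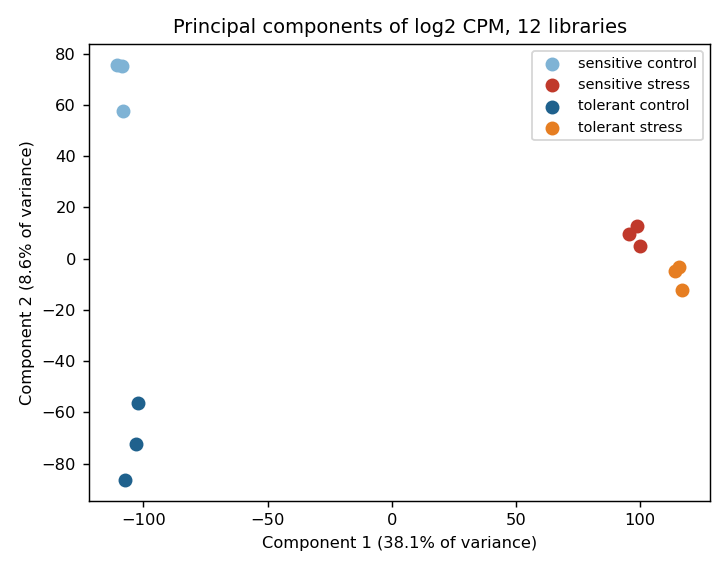
Principal components of log2 CPM of the 12 libraries, coloured by line and treatment. The first component holds 38.1% of the variance and the second 8.61%.

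The first comparison asked which transcripts changed under high night temperature in the sensitive line. Heat shock protein transcripts rose. HSP90 (LOC_Os04g01740, chromosome 4, 483241 to 486065), a cytosolic chaperone, rose from 1.47 ± 0.684 to 303 ± 3.01 CPM (counts scaled to library size; mean ± SD, n = 3), a log2 fold change of 7.68 ± 0.32 (SE; adjusted p = 3.84e-09). The small heat shock proteins HSP23.2 (LOC_Os04g36750, chromosome 4, 22200999 to 22201941) and HSP26.7 (LOC_Os03g14180, chromosome 3, 7697015 to 7698284) rose by log2 5.77 ± 0.29 and 5.51 ± 0.31, and mitochondrial HSP24.1 (LOC_Os02g52150, chromosome 2, 31920854 to 31922712) rose by 4.99 ± 0.11. HSC70-1 (LOC_Os01g62290, chromosome 1, 36039706 to 36043510) rose from 64.1 ± 1.196 to 357.5 ± 9.199 CPM, and an HSP70 gene (LOC_Os03g16920, chromosome 3, 9371953 to 9416082) rose from 82.8 ± 3.27 to 441.5 ± 8.78 CPM. A 70 kDa peptidyl-prolyl isomerase (LOC_Os04g28420, chromosome 4, 16813848 to 16818129) rose by log2 5.24 ± 0.13. Of the 39 tested heat shock proteins, 29 rose, 2 fell and 8 did not pass (30 rose and 3 fell when adjusted over the list alone). The list median log2 fold change was 1.84. The list rose against all other genes in the camera test (adjusted p = 8.48e-15; adjusted p = 0.000109 with an estimated correlation).

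Some chaperones of the endoplasmic reticulum (ER) rose in the sensitive line. BiP1 (LOC_Os02g02410, chromosome 2, 838717 to 842672), the Hsp70 of the ER lumen, rose from 789 ± 14.7 to 1529 ± 7.325 CPM, a log2 fold change of 0.95 ± 0.03. GRP94 (LOC_Os06g50300, chromosome 6, 30444411 to 30450497), the Hsp90 of the ER, rose by 1.75 ± 0.09, and the disulfide isomerase PDIL2-3 (LOC_Os09g27830, chromosome 9, 16930987 to 16935970) rose by 1.21 ± 0.07. Of 25 tested ER stress and protein folding genes, 10 rose and 5 fell (12 and 5 adjusted over the list alone). The list median was 0.46 with adjusted p = 0.0111. That call was lost at adjusted p = 0.0588 with an estimated correlation. Among 26 heat stress transcription factors, 8 rose and 5 fell (10 and 5 adjusted over the list alone). HsfA3 (LOC_Os02g32590) rose by log2 3.94 ± 0.23, HsfB2c (LOC_Os09g35790) by 1.78 ± 0.07 and HsfB2b (LOC_Os08g43334) by 1.41 ± 0.09, while the list as a whole did not pass (adjusted p = 0.0871).

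Transcripts of seed storage proteins and of starch synthesis fell in the sensitive line. Glb1 (LOC_Os05g41970, chromosome 5, 24576897 to 24577736), the 19 kDa globulin of the endosperm, fell from 8064 ± 69.97 to 1776 ± 79.8 CPM, a log2 fold change of -2.18 ± 0.04 (adjusted p = 1.16e-11). A table entry that merges the glutelin loci of GluB1 and GluB2 (LOC_Os02g15150 and LOC_Os02g15169 and LOC_Os02g15178, chromosome 2, 8402491 to 8467151) changed by -1.20 ± 0.05, and NAC20 (LOC_Os01g01470, chromosome 1, 241641 to 243468), a transcription factor that activates storage protein genes, by -1.07 ± 0.04. Of 28 tested storage proteins and regulators, 0 rose and 21 fell (0 and 22 adjusted over the list alone). Their median was -0.99 (adjusted p = 1.37e-14; adjusted p = 0.00234 with an estimated correlation). The starch-branching enzymes BEI (LOC_Os06g51084, chromosome 6, 30897376 to 30905803) and BEIIb (LOC_Os02g32660, chromosome 2, 19355748 to 19367127) changed by -1.30 ± 0.03 and -1.33 ± 0.05. AGPS2 (LOC_Os08g25734, chromosome 8, 15666201 to 15672594), a small subunit of ADP-glucose pyrophosphorylase, fell from 2442 ± 49.9 to 1262 ± 18.5 CPM. In the starch list, 17 of 30 tested genes fell and 6 rose (17 and 8 adjusted over the list alone). The median of the list was -0.47 (adjusted p = 5.85e-05; adjusted p = 0.025 with an estimated correlation). Starch synthase SSI (LOC_Os06g06560) and sucrose synthase SUS3 (LOC_Os07g42490) were among those that rose, by log2 1.17 ± 0.07 and 0.99 ± 0.05; both were named after their values were seen.

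Transcripts of cytosolic ribosomal proteins were also lower under stress in the sensitive line, set against the median gene. Of 148 tested genes, 95 fell and 7 rose (100 and 9 adjusted over the list alone). The members had a median of -0.53 (adjusted p = 1.54e-20; adjusted p = 0.000109 with an estimated correlation). With library totals alone that median was -0.11 and that of the starch list -0.06, so how far either fell depends on the scaling. The 60S protein gene L13-2 (LOC_Os03g37970, chromosome 3, 21086229 to 21088565) fell from 254.5 ± 1.545 to 104 ± 3.815 CPM. The 40S gene S11 (LOC_Os04g42380, chromosome 4, 25076764 to 25079041) changed by log2 -1.69 ± 0.09 and the 60S gene L7-3 (LOC_Os08g13690, chromosome 8, 8153369 to 8155981) by -1.12 ± 0.06.

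The remaining lists did not pass in the sensitive line, although single members did. The morning clock gene LHY (LOC_Os08g06110, chromosome 8, 3360802 to 3373434) fell from 359 ± 28.55 to 121 ± 8.04 CPM, while PRR1 (LOC_Os02g40510) and GI (LOC_Os01g08700) rose by log2 1.28 ± 0.20 and 0.46 ± 0.07. Of 10 clock genes, 5 rose and 1 fell (6 and 1 adjusted over the list alone; list adjusted p = 0.168). Among abscisic acid genes, the synthesis gene NCED5 (LOC_Os12g42280) changed by -1.69 ± 0.16, NCED4 (LOC_Os07g05940) by 1.52 ± 0.15 and the catabolic gene ABA8OX1 (LOC_Os02g47470) by 1.81 ± 0.20, with 4 of 8 up and 1 down (5 and 2 adjusted over the list alone; list adjusted p = 0.168). Cytosolic ascorbate peroxidase APX1 (LOC_Os03g17690) rose by 0.91 ± 0.06 and catalase CATB (LOC_Os06g51150) by 0.61 ± 0.06. Of 21 antioxidant genes, 9 rose and 4 fell (10 and 4 adjusted over the list alone; list adjusted p = 0.0871). The embryo gene OLE16 (LOC_Os04g46200), an oleosin, changed by -0.58 ± 0.04. Of 26 embryo and late maturation genes, 12 rose and 6 fell (13 and 7 adjusted over the list alone; list adjusted p = 0.13).

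Of 53 conserved microRNA target genes, 7 rose and 15 fell in the sensitive line (8 and 19 adjusted over the list alone; list adjusted p = 0.109). HOX10 (LOC_Os03g01890), a class III HD-ZIP gene of the miR166 target family, changed by log2 -1.02 ± 0.08, and RSR1 (LOC_Os05g03040), an AP2 gene known as a regulator of starch synthesis, by -1.01 ± 0.10. In the microRNA machinery, argonaute AGO18 (LOC_Os07g28850) rose by 1.41 ± 0.14 and AGO12 (LOC_Os03g47820) changed by -1.61 ± 0.15. Of 26 machinery genes, 6 rose and 4 fell (6 and 4 adjusted over the list alone; list adjusted p = 0.314). The photosystem II 10 kDa gene (LOC_Os07g05360) changed by -1.75 ± 0.11, and 8 of 44 photosynthesis genes rose while 17 fell (9 and 18 adjusted over the list alone; list adjusted p = 0.109). A histone H1 gene (LOC_Os06g04020) changed by -1.08 ± 0.08. Of 14 histone genes, 1 rose and 4 fell, with the same counts when adjusted over the list alone (list adjusted p = 0.325), and the list's median of -0.03 and mean of 0.20 differed in sign. Of 8 alpha-amylases, 2 rose and 2 fell (2 and 3 adjusted over the list alone; list adjusted p = 0.752), among them Amy3E (LOC_Os08g36900, chromosome 8, 23335165 to 23337151), which rose from 36.9 ± 2.16 to 45.7 ± 1.29 CPM.

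Over all 33281 tested genes, 10695 changed in the sensitive line in the edgeR test at an adjusted p under 0.05, 5416 up and 5279 down, and 4656 of them changed at least 2-fold, 2823 up and 1833 down. For the called genes of the naming rule, here and in the next 3 comparisons, 3 of 3 libraries of a group lay on the same side of the other group. Their selection favours this, so it adds no evidence. Among the largest falls were laccase-10 (LOC_Os03g16610, chromosome 3, 9167558 to 9170334), at -3.68 ± 0.13, aquaporin PIP2-4 (LOC_Os07g26630 and LOC_Os07g26640, chromosome 7, 15358960 to 15370166), at -3.96 ± 0.38, and HEADING DATE 3A (LOC_Os06g06320, chromosome 6, 2940004 to 2942878), the florigen gene, at -3.46 ± 0.10. Scaling set the split: normalization factors were 0.838 to 0.981 in control and 1.11 to 1.18 under stress, and with library totals alone 83.6% of called genes were higher (82.2% in FPKM) against 50.6%, and the median log2 fold change of all genes was 0.46 in place of 0.04. All changes are given on the TMM scale, which puts the median gene near 0. A cytochrome b559 locus (LOC_Os06g39728), a ubiquitin-ribosomal protein locus (LOC_Os03g13170) and an ethylene-responsive factor locus (LOC_Os08g31580) were also among the largest changes, but their counts jumped between replicates of a group.

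**Figure D2:**
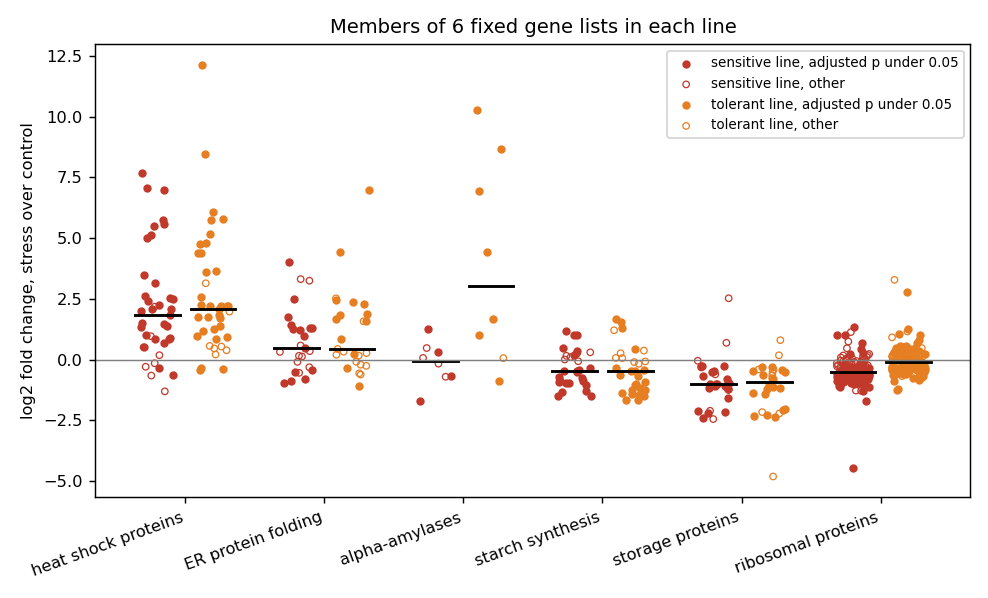
Log2 fold changes under stress of the members of 6 gene lists in each line, with filled points for an adjusted p under 0.05 and a black line at the median. The median of the ribosomal list in the tolerant line, -0.10, turned to 0.22 with library totals alone.

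The second comparison asked the same in the tolerant line. HSP90 (LOC_Os04g01740) rose from 1.245 ± 0.355 to 436.5 ± 11.5 CPM, a log2 fold change of 8.45 ± 0.33 (adjusted p = 1.41e-09). HSP23.2 (LOC_Os04g36750) rose by 6.10 ± 0.30, HSP24.1 (LOC_Os02g52150) by 5.75 ± 0.11, the 70 kDa peptidyl-prolyl isomerase (LOC_Os04g28420) by 5.84 ± 0.13 and HSC70-1 (LOC_Os01g62290) by 2.58 ± 0.05. Of 39 heat shock proteins, 29 rose and 3 fell, with the same counts when adjusted over the list alone, and the median was 2.09 (adjusted p = 1.86e-16; adjusted p = 0.000123 with an estimated correlation). BiP1 (LOC_Os02g02410) rose from 732 ± 9.61 to 2223 ± 27.02 CPM, GRP94 (LOC_Os06g50300) from 48.7 ± 3.99 to 264 ± 14.7 CPM and PDIL2-3 (LOC_Os09g27830) from 38.5 ± 2.09 to 189 ± 3.065 CPM. Of 25 ER genes, 11 rose and 2 fell (12 and 2 adjusted over the list alone). The list median was 0.44 (adjusted p = 7.39e-05; adjusted p = 0.0106 with an estimated correlation). Heat stress factors HsfB2c (LOC_Os09g35790), HsfB2b (LOC_Os08g43334) and HsfA2c (LOC_Os10g28340, chromosome 10, 14746101 to 14750175) rose by 2.06 ± 0.07, 1.84 ± 0.09 and 1.68 ± 0.09. In their list 10 of 26 rose and 4 fell (10 and 5 adjusted over the list alone). Its median was 0.32 with adjusted p = 0.0479, lost at adjusted p = 0.0755 with an estimated correlation and without any 1 of 4 libraries (adjusted p = 0.0505 to 0.0810).

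Storage and starch transcripts fell in the tolerant line. Glb1 (LOC_Os05g41970) fell from 6782 ± 323 to 1609 ± 43.4 CPM, a log2 fold change of -2.08 ± 0.04, and glutelin GluB4 (LOC_Os02g16830, chromosome 2, 9586007 to 9588016) fell from 6472 ± 550.4 to 2858 ± 48.6 CPM. Of 28 storage genes, 0 rose and 19 fell (0 and 20 adjusted over the list alone). Their median was -0.92 (adjusted p = 3.20e-13; adjusted p = 0.00472 with an estimated correlation). Wx (LOC_Os06g04200, chromosome 6, 1764660 to 1770656), the granule-bound starch synthase that makes amylose, fell from 4932 ± 149.9 to 1723 ± 27.2 CPM, a log2 fold change of -1.52 ± 0.04 (adjusted p = 4.76e-11). BEI (LOC_Os06g51084) changed by -1.45 ± 0.03 and the pyruvate, phosphate dikinase PPDKB (LOC_Os05g33570, chromosome 5, 19718506 to 19726410) by -1.18 ± 0.03. Of 30 starch genes, 18 fell and 4 rose (18 and 5 adjusted over the list alone). The median of the list was -0.46 (adjusted p = 2.29e-06; adjusted p = 0.0106 with an estimated correlation), and -0.15 with library totals alone.

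Alpha-amylase transcripts rose in the tolerant line, from a summed 85.6 ± 3.80 CPM in control to 207 ± 6.70 CPM under stress. Amy3E (LOC_Os08g36900) rose from 46.9 ± 1.83 to 148 ± 7.798 CPM, a log2 fold change of 1.66 ± 0.07 (adjusted p = 1.79e-09). Amy3A (LOC_Os09g28400, chromosome 9, 17288993 to 17291295) rose from 0.01575 ± 0.0273 to 21.05 ± 1.66 CPM, with 0, 0 and 4 counts in the control libraries. Amy3D (LOC_Os08g36910, chromosome 8, 23340676 to 23343533) rose from 0.063 ± 0.109 to 7.896 ± 1.615 CPM. Of 8 tested alpha-amylases, 6 rose and 1 fell, with the same counts when adjusted over the list alone (adjusted p = 0.00101; adjusted p = 0.0179 with an estimated correlation). The call was lost in FPKM with a pseudocount of 0.1 (adjusted p = 0.0525).

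Cytosolic ribosomal protein genes went both ways in the tolerant line, with 52 of 148 down and 21 up (54 and 24 adjusted over the list alone). Their median of -0.10 (adjusted p = 0.00612; adjusted p = 0.043 with an estimated correlation) turned to 0.22 with library totals alone and 0.23 in FPKM, so the direction of the list rests on the scaling. L13-2 (LOC_Os03g37970) fell from 233 ± 4.62 to 96.7 ± 0.769 CPM, and S11 (LOC_Os04g42380) changed by log2 -1.19 ± 0.09. Conserved microRNA targets had 5 of 53 up and 19 down (7 and 20 adjusted over the list alone), with HOX10 (LOC_Os03g01890) at -1.03 ± 0.08, OSHB3 (LOC_Os12g41860) at -1.30 ± 0.11 and RSR1 (LOC_Os05g03040) at -1.09 ± 0.10. Their list median was -0.23 (adjusted p = 0.0342; adjusted p = 0.043 with an estimated correlation), 0.10 with library totals alone (adjusted p = 0.119) and 0.03 in FPKM (adjusted p = 0.0708), and the call was also lost without tolerant control 2 (0.0527) and without tolerant stress 3 (0.0767). Photosynthesis genes had 8 of 44 up and 16 down (8 and 19 adjusted over the list alone), among them RCA (LOC_Os11g47970, chromosome 11, 28932979 to 28936053), the Rubisco activase, which fell from 334 ± 11.7 to 158 ± 5.04 CPM. Their median was -0.17 with adjusted p = 0.0212, lost at adjusted p = 0.224 with an estimated correlation, and 0.14 with library totals alone.

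The other lists did not pass in the tolerant line. LHY (LOC_Os08g06110) fell from 461 ± 31.15 to 112 ± 2.99 CPM, and 5 of 10 clock genes rose while 1 fell, with the same counts when adjusted over the list alone (list adjusted p = 0.54). APX1 (LOC_Os03g17690) rose by log2 1.11 ± 0.06, and 9 of 21 antioxidant genes rose and 4 fell, with the same counts when adjusted over the list alone (list adjusted p = 0.141). NCED4 (LOC_Os07g05940) rose by 2.06 ± 0.15. Of 8 abscisic acid genes, 4 were up and 2 down (5 and 2 adjusted over the list alone; list adjusted p = 0.326). OLE16 (LOC_Os04g46200) and OLE18 (LOC_Os03g49190) changed by -1.05 ± 0.04 and -0.82 ± 0.04. Of 26 embryo genes, 9 rose and 7 fell (10 and 7 adjusted over the list alone; list adjusted p = 0.71). In the microRNA machinery, where 10 of 26 rose and 5 fell with the same counts when adjusted over the list alone (list adjusted p = 0.43), AGO12 (LOC_Os03g47820) changed by -2.18 ± 0.16 and DCL2b (LOC_Os09g14610) by 0.78 ± 0.08. Histone genes had 0 of 14 up and 3 down (0 and 1 adjusted over the list alone; list adjusted p = 0.362), with histone H1 (LOC_Os06g04020) at -1.15 ± 0.08.

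In all, 11059 genes changed in the tolerant line, 5547 up and 5512 down, and 5079 changed at least 2-fold, 2986 up and 2093 down. Expansin-B15 (LOC_Os04g46630, chromosome 4, 27645595 to 27647517) rose from 0.3275 ± 0.205 to 23.16 ± 1.67 CPM and basic 7S globulin 2 (LOC_Os01g71080, chromosome 1, 41139174 to 41140671) from 0.173 ± 0.161 to 21.1 ± 0.7955 CPM. Laccase-10 (LOC_Os03g16610), nitrate reductase 1 (LOC_Os08g36480, chromosome 8, 23033230 to 23038596) and cinnamoyl-CoA reductase 1 (LOC_Os09g25150, chromosome 9, 15076124 to 15079326), a lignin pathway enzyme, changed by log2 -5.16 ± 0.14, -4.21 ± 0.16 and -3.39 ± 0.05. With library totals alone 76.8% of called genes were higher (76.2% in FPKM) against 50.2%, and the median of all genes was 0.37 in place of 0.05. The responses of the lines overlapped: 3760 genes rose in both, where 903 were expected by chance, 3865 fell in both, where 874 were expected, and 75 changed in opposite directions. Across the 14054 genes called in either line the log2 fold changes had a Pearson r of 0.711 and 92.7% had the same sign, though genes are not independent replicates.

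**Figure D3:**
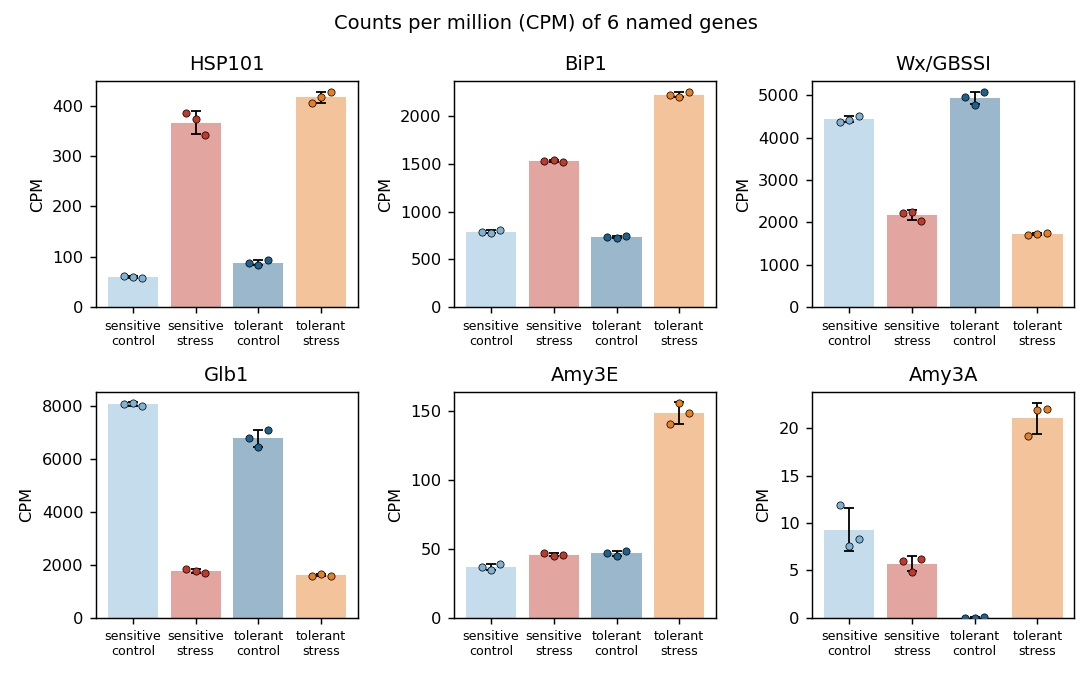
CPM of 6 named genes in the 4 groups, as mean ± SD with 1 point per library (n = 3). HSP101 and BiP1 rose in both lines and Wx and Glb1 fell in both, while Amy3A was near 0 in the tolerant line in control.

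The third comparison set the tolerant line against the sensitive line in control. Cytosolic ribosomal protein genes were lower in the tolerant line: 102 of 148 passed as lower and 0 as higher (119 and 1 adjusted over the list alone), and with library totals alone 55 and 0 passed. The members had a median of -0.49 (adjusted p = 1.01e-64; adjusted p = 2.52e-06 with an estimated correlation). The 40S gene S2-3 (LOC_Os07g10660, chromosome 7, 5787215 to 5789245) stood at 21.5 ± 0.415 CPM against 37.5 ± 2.002, an L9-like 60S gene (LOC_Os02g01332, chromosome 2, 180320 to 183442) at 18.3 ± 0.632 against 33.7 ± 0.502, and the 40S gene S13-1 (LOC_Os08g02400 and LOC_Os08g02410, chromosome 8, 956309 to 964533) at 64.2 ± 1.14 against 100.2 ± 3.74. Some alpha-amylases were lower, with Amy3A (LOC_Os09g28400) at 0.01575 ± 0.0273 CPM against 9.26 ± 2.27, Amy3D (LOC_Os08g36910) at 0.063 ± 0.109 against 4.48 ± 0.743 and Amy1A (LOC_Os02g52710, chromosome 2, 32248279 to 32250180) at 0.0352 ± 0.0309 against 1.33 ± 0.441. The most abundant, Amy3E (LOC_Os08g36900), was higher, at 46.9 ± 1.83 CPM against 36.9 ± 2.16 (adjusted p = 0.00875), and the list summed to 85.6 ± 3.80 CPM against 95.9 ± 4.06. Of 8 alpha-amylases, 4 were lower and 1 higher, with the same counts when adjusted over the list alone (adjusted p = 1.86e-05; adjusted p = 0.00772 with an estimated correlation). ER genes had 3 of 25 lower and 0 higher (7 and 0 adjusted over the list alone), with PDIL2-3 (LOC_Os09g27830) at -0.46 ± 0.07 and a list median of -0.21 (adjusted p = 1.86e-05; adjusted p = 0.00772 with an estimated correlation).

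Embryo genes were higher in the tolerant line in control in 3 of 26 cases and lower in 0 (6 and 0 adjusted over the list alone), with LEA19 (LOC_Os05g46480) at log2 0.57 ± 0.09 and a median of 0.17 (adjusted p = 0.00634), lost at adjusted p = 0.157 with an estimated correlation. Photosynthesis genes had 2 of 44 higher, RCA (LOC_Os11g47970) among them at 0.35 ± 0.05, and 4 lower (3 and 5 adjusted over the list alone). Their median was -0.11 with adjusted p = 0.00634, lost at adjusted p = 0.201 with an estimated correlation, without sensitive control 1 (0.0568), without tolerant control 2 (0.0637), with library totals alone (0.202) and in FPKM (0.144). HSP101 (LOC_Os05g44340, chromosome 5, 25803530 to 25807160), the ClpB disaggregase, stood at 88.03 ± 4.603 CPM against 59.3 ± 2.17, and the HSP70 gene LOC_Os03g16920 was higher by log2 0.52 ± 0.05, while the heat shock list had 4 of 39 higher and 1 lower (6 and 4 adjusted over the list alone; list adjusted p = 0.594). Glutelins GluB4 (LOC_Os02g16830) and GluB5 (LOC_Os02g16820) were higher by 0.51 ± 0.05 and 0.52 ± 0.05. Of 28 storage genes, 6 were higher and 3 lower (6 and 5 adjusted over the list alone; list adjusted p = 0.442). Sucrose synthases SUS3 (LOC_Os07g42490) and SUS4 (LOC_Os03g22120, chromosome 3, 12674462 to 12680657) differed by -0.65 ± 0.05 and 0.36 ± 0.04. Of 30 starch genes, 3 were higher and 7 lower (6 and 8 adjusted over the list alone; list adjusted p = 0.288).

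The other lists did not pass between the lines in control. Abscisic acid genes had 0 of 8 higher and 1 lower (3 and 2 adjusted over the list alone; list adjusted p = 0.502). Antioxidant enzymes had 2 of 21 higher and 0 lower (4 and 1 adjusted over the list alone; list adjusted p = 0.887). Clock genes had 1 of 10 higher and 0 lower (1 and 0 adjusted over the list alone; list adjusted p = 0.0995). MicroRNA targets had 1 of 53 higher and 0 lower (1 and 0 adjusted over the list alone; list adjusted p = 0.185). MicroRNA machinery genes had 2 of 26 higher and 0 lower (4 and 0 adjusted over the list alone; list adjusted p = 0.0995). Heat stress factors had 1 of 26 higher and 0 lower (1 and 1 adjusted over the list alone; list adjusted p = 0.251). Histone genes had 0 of 14 higher and 0 lower (0 and 0 adjusted over the list alone; list adjusted p = 0.594). Over all genes 1804 differed, 841 higher and 963 lower in the tolerant line, and 315 differed at least 2-fold, 140 higher and 175 lower. Reticulon-like protein B2 (LOC_Os06g30750, chromosome 6, 17836886 to 17840919) stood at 243 ± 2.66 CPM against 119.9 ± 4.37, chitinase 1 (LOC_Os06g51060, chromosome 6, 30890711 to 30892066) at 5.12 ± 0.332 against 21.7 ± 1.01, non-specific lipid-transfer protein 1 (LOC_Os03g59380, chromosome 3, 33798940 to 33799765) at 18.4 ± 2.07 against 69.7 ± 5.596 and early nodulin-like protein 3 (LOC_Os08g17160, chromosome 8, 10508124 to 10509239) at 4.53 ± 0.868 against 16.96 ± 0.964. With library totals alone 75.2% of called genes were higher (67.9% in FPKM) against 46.6%, the median of all genes moved from 0.00 to 0.11, and without tolerant control 1 the count was 1098.

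The fourth comparison set the lines against each other under stress. The heat shock list was higher in the tolerant line, though few of its genes passed: 6 of 39 passed as higher and 1 as lower (8 and 1 adjusted over the list alone). The list median was 0.18 (adjusted p = 9.56e-05; adjusted p = 0.00696 with an estimated correlation). HSC71 (LOC_Os11g47760, chromosome 11, 28804248 to 28808550) stood at 2395 ± 26.3 CPM against 1995 ± 20.2 and HSC70-1 (LOC_Os01g62290) at 459 ± 10.55 against 357.5 ± 9.199. ER genes had 5 of 25 higher and 0 lower (6 and 2 adjusted over the list alone), with BiP1 (LOC_Os02g02410) at 2223 ± 27.02 CPM against 1529 ± 7.325, GRP94 (LOC_Os06g50300) at 264 ± 14.7 against 182 ± 9.605, and a list median of 0.11 (adjusted p = 0.00614; adjusted p = 0.0405 with an estimated correlation). HsfB2b (LOC_Os08g43334) and HsfA2c (LOC_Os10g28340) were higher by log2 0.54 ± 0.09 and 0.53 ± 0.09, and 3 of 26 heat stress factors were higher and 0 lower (5 and 0 adjusted over the list alone). Their median was 0.09 (adjusted p = 0.00614; adjusted p = 0.0265 with an estimated correlation). Amy3E (LOC_Os08g36900) stood at 148 ± 7.798 CPM against 45.7 ± 1.29 and Amy3A (LOC_Os09g28400) at 21.05 ± 1.66 against 5.68 ± 0.784. Of 8 alpha-amylases, 3 were higher and 1 lower (3 and 2 adjusted over the list alone; list adjusted p = 0.0244). That list call was lost at adjusted p = 0.0659 with an estimated correlation and without sensitive stress 1 (adjusted p = 0.0888).

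The starch, photosynthesis and ribosomal protein lists were lower in the tolerant line under stress, with a minority of their genes called. PPDKB (LOC_Os05g33570) stood at 696.5 ± 13.95 CPM against 1015 ± 10.6, AGPS2 (LOC_Os08g25734) at 886 ± 4.78 against 1262 ± 18.5 and SUS2 (LOC_Os06g09450, chromosome 6, 4796286 to 4804237) at 456 ± 13.3 against 622 ± 18.9. Of 30 starch genes, 10 were lower and 1 higher (13 and 1 adjusted over the list alone). Their median was -0.11 (adjusted p = 6.59e-08; adjusted p = 0.00696 with an estimated correlation). The Rubisco small subunit RBCS4 (LOC_Os12g19470, chromosome 12, 11320267 to 11322547) and plastocyanin (LOC_Os06g01210, chromosome 6, 149384 to 150246) differed by log2 -0.64 ± 0.08 and -0.52 ± 0.08. Of 44 photosynthesis genes, 7 were lower and 1 higher (12 and 1 adjusted over the list alone). The median of the list was -0.17 (adjusted p = 1.34e-08; adjusted p = 0.022 with an estimated correlation). Of 148 ribosomal protein genes, 4 were lower and 0 higher (1 and 0 adjusted over the list alone). The members had a median of -0.13 (adjusted p = 4.18e-09; adjusted p = 0.0042 with an estimated correlation). Glutelin GluA1 (LOC_Os01g55690, chromosome 1, 32076732 to 32078743) was higher, at 15120 ± 259.9 CPM against 11470 ± 388. Of 28 storage genes, 3 were higher and 2 lower (5 and 6 adjusted over the list alone; list adjusted p = 0.67). OLE16 (LOC_Os04g46200) was lower, at 912 ± 22.5 CPM against 1202 ± 44.7. Of 26 embryo genes, 1 was higher and 3 lower (1 and 6 adjusted over the list alone; list adjusted p = 0.246).

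The other lists did not pass between the lines under stress. Abscisic acid genes had 0 of 8 higher and 1 lower (1 and 2 adjusted over the list alone; list adjusted p = 0.67). Antioxidant enzymes had 0 of 21 higher and 0 lower (0 and 0 adjusted over the list alone; list adjusted p = 0.67). Clock genes had 0 of 10 higher and 0 lower (0 and 0 adjusted over the list alone; list adjusted p = 0.696). MicroRNA targets had 0 of 53 higher and 0 lower (0 and 0 adjusted over the list alone; list adjusted p = 0.696). MicroRNA machinery genes had 2 of 26 higher and 0 lower (2 and 1 adjusted over the list alone; list adjusted p = 0.151). Histone genes had 0 of 14 higher and 0 lower (0 and 0 adjusted over the list alone; list adjusted p = 0.688). Over all genes 1132 differed, 568 higher and 564 lower in the tolerant line, and 235 differed at least 2-fold, 153 higher and 82 lower. Chitinase 1 (LOC_Os06g51060) stood at 20.2 ± 0.608 CPM against 4.42 ± 0.868, a locus annotated as a truncated CAULIFLOWER transcription factor (LOC_Os04g31790 and LOC_Os04g31804, chromosome 4, 19020372 to 19060918) at 44.97 ± 0.961 against 11.5 ± 3.27, germacrene A oxidase (LOC_Os02g09310, chromosome 2, 4791383 to 4793372) at 52.01 ± 1.16 against 16.7 ± 1.08 and the cellulose synthase CESA7 (LOC_Os10g32980, chromosome 10, 17261952 to 17266613) at 12.4 ± 0.978 against 31.8 ± 2.24. Of the genes that differed in both comparisons of the lines, 105 were higher and 99 lower in the tolerant line each time, where 14.4 and 16.3 were expected by chance, and 94 differed in opposite directions. The chance numbers take the calls of the 2 comparisons as independent, although some genes are easier to call in both. No chance number was computed for opposite directions, so how much of the excess is a stable difference between the lines is not known. The count was 696 with library totals alone and 672, 703, 688 and 716 without sensitive stress 1, sensitive stress 2, tolerant stress 1 and tolerant stress 3.

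The fifth comparison tested whether the stress response differed between the lines, as the response of the tolerant line minus that of the sensitive line. Some ER chaperones rose more in the tolerant line: BiP1 (LOC_Os02g02410) by log2 0.65 ± 0.04 (adjusted p = 7.59e-06) and PDIL2-3 (LOC_Os09g27830) by 1.08 ± 0.10. Of 25 genes, 5 were positive and 0 negative (10 and 0 adjusted over the list alone), with a median of 0.32 (adjusted p = 2.29e-07; adjusted p = 0.00294 with an estimated correlation). Between the lines the list median was -0.21 in control and 0.11 under stress, so a lower level in control enters the list's difference. Alpha-amylases also differed, with Amy3E (LOC_Os08g36900) at 1.35 ± 0.09, 5 of 8 positive and 0 negative, and the same counts when adjusted over the list alone (adjusted p = 1.05e-09; adjusted p = 0.00122 with an estimated correlation). The difference in response was positive for part of the ribosomal protein genes, such as the 60S gene L9 (LOC_Os09g31180, chromosome 9, 18751895 to 18754232), which fell from 124 ± 4.16 to 62.1 ± 1.22 CPM in the sensitive line and stood at 73.9 ± 8.495 and 66.6 ± 5.39 CPM in the tolerant line. In that list 29 of 148 were positive and 0 negative (76 and 0 adjusted over the list alone). The list median was 0.37 (adjusted p = 5.37e-34; adjusted p = 3.15e-05 with an estimated correlation).

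Some starch genes fell further in the tolerant line: SUS4 (LOC_Os03g22120) by log2 -0.63 ± 0.06, BT1 (LOC_Os02g10800, chromosome 2, 5736604 to 5738853), the ADP-glucose transporter, by -0.55 ± 0.06 and Wx (LOC_Os06g04200) by -0.49 ± 0.06. In the list 7 of 30 were negative and 2 positive (8 and 2 adjusted over the list alone). Its median was -0.11 with adjusted p = 0.000938, lost at adjusted p = 0.0554 with an estimated correlation. Embryo genes had 3 of 26 negative, OLE16 (LOC_Os04g46200) at -0.47 ± 0.06 among them, and 0 positive (7 and 0 adjusted over the list alone). Their median was -0.26 with adjusted p = 0.000701, lost at adjusted p = 0.0554 with an estimated correlation. Heat shock proteins had 1 of 39 positive and 2 negative (4 and 3 adjusted over the list alone), with HSP24.1 (LOC_Os02g52150) at 0.76 ± 0.13, a call lost with library totals alone. The list median was 0.24 with adjusted p = 0.04, lost at adjusted p = 0.0554 with an estimated correlation, without any 1 of 7 libraries (adjusted p = 0.0506 to 0.123), in FPKM (0.185) and with library totals alone (0.0908). RCA (LOC_Os11g47970) differed by -0.49 ± 0.07. Like SUS4, RCA stood higher in the tolerant line in control, and that level enters its difference in response. Of 44 photosynthesis genes, 2 were negative and 0 positive (3 and 0 adjusted over the list alone; list adjusted p = 0.0609). That list passed as negative without sensitive control 1, tolerant control 1, tolerant control 2 or tolerant stress 2 (adjusted p = 0.0159 to 0.0361). NAC20 (LOC_Os01g01470) differed by 0.31 ± 0.06, a call lost with library totals alone. Of 28 storage genes, 2 were positive and 0 negative (3 and 1 adjusted over the list alone; list adjusted p = 0.866).

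The other lists did not pass in the test of the difference. Abscisic acid genes had 0 of 8 positive and 0 negative (1 and 1 adjusted over the list alone; list adjusted p = 0.877). Antioxidant enzymes had 0 of 21 positive and 0 negative (0 and 2 adjusted over the list alone; list adjusted p = 0.645). Clock genes had 0 of 10 positive and 1 negative (0 and 1 adjusted over the list alone; list adjusted p = 0.112). MicroRNA targets had 0 of 53 positive and 0 negative (0 and 0 adjusted over the list alone; list adjusted p = 0.406). MicroRNA machinery genes had 0 of 26 positive and 0 negative (0 and 1 adjusted over the list alone; list adjusted p = 0.866). Heat stress factors had 0 of 26 positive and 0 negative (0 and 0 adjusted over the list alone; list adjusted p = 0.364). Histone genes had 0 of 14 positive and 0 negative (0 and 0 adjusted over the list alone; list adjusted p = 0.877). Over all genes 867 differed in response, 422 positive and 445 negative, and 274 differed at least 2-fold, 181 positive and 93 negative. Of these 867, 449 changed in both lines in the same direction, 74 in both in opposite directions, 138 passed in the sensitive line alone and 206 in the tolerant line alone. Chitinase 1 (LOC_Os06g51060) fell from 21.7 ± 1.01 to 4.42 ± 0.868 CPM in the sensitive line and rose from 5.12 ± 0.332 to 20.2 ± 0.608 CPM in the tolerant line, and amino acid permease 3 (LOC_Os12g08090, chromosome 12, 4120926 to 4123058) rose from 8.24 ± 1.001 to 24.5 ± 1.07 CPM in the sensitive line and stood at 10.5 ± 1.46 and 9.79 ± 2.32 CPM in the tolerant line. With library totals alone 32.0% of called genes were positive (33.4% in FPKM) against 48.7%, and the median of all genes was -0.10 in place of 0.00.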

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

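Most results here were picked because the stress response differed between the lines in a test of the difference itself (tolerant minus sensitive, log2), with the response of the sensitive and then the tolerant line in brackets. The splits of the other comparisons, the lower ribosomal level in control and the genes set against chromosome segments did not come from that test. The test of scaling for the ribosomal list, its bound included, and the tests of alpha-amylases were chosen only after the values were seen, as was that of windows, and the other tests were set before theirs. The ribosomal and alpha-amylase patterns were themselves picked from list tests already seen.

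In all, 867 genes differed in response. Only 1 of 40 splits of the libraries drawn from 200 possible, the real one, gave as many, and the highest other gave 143. The other splits mix the lines, whose differences widen the spread and lower the calls, and 1 of 40 is the smallest share possible. The splits therefore do not exclude chance. For stress in the sensitive line (10695 genes; highest other split 1), stress in the tolerant line (11059; 1), the lines in control (1804; 6) and the lines under stress (1132; 3), 1 of 10 splits gave as many, the real one, and 10 splits are too few for a share under 0.05. The chaperone and ER lists differed by a median of 0.24 for heat shock proteins (1.84, 2.09; adjusted p = 0.0400; adjusted p = 0.0554 with an estimated correlation) and 0.32 for ER protein folding (0.46, 0.44; adjusted p = 2.29e-07). The embryo list differed by -0.26 (0.35, 0.26; adjusted p = 0.000701; adjusted p = 0.0554 with an estimated correlation) and the starch list by -0.11 (-0.47, -0.46; adjusted p = 0.000938; adjusted p = 0.0554 with an estimated correlation). Medians of a difference need not equal the difference of the medians.

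Chaperone genes that differed were PDIL2-3 (LOC_Os09g27830) by 1.08 (1.21, 2.29; adjusted p = 8.85e-05), HSP24.1 (LOC_Os02g52150) by 0.76 (4.99, 5.75; 0.00877), GRP94 (LOC_Os06g50300) by 0.68 (1.75, 2.44; 0.0123), BiP1 (LOC_Os02g02410) by 0.65 (0.95, 1.602; 7.59e-06) and PDIL1-1 (LOC_Os11g09280) by 0.32 (-0.09, 0.23; 0.00908). HSP70 (LOC_Os03g16920) rose less in the tolerant line, by -0.32 (2.42, 2.09; 0.0245), as did HSP101 (LOC_Os05g44340), by -0.39 (2.63, 2.24; 0.0282). Those calls were lost without any 1 of 7 libraries for HSP70 (adjusted p = 0.0542 to 0.0705) and of 8 for HSP101 (0.0547 to 0.0822). Neither gene was lower in the tolerant line under stress. HSP70 was higher there by log2 0.52 in control and 0.20 under stress. HSP101 stood at 83.3 to 92.5 CPM against 57.1 to 61.4 in control and at 405 to 427 against 341 to 385 under stress.

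Starch and storage genes that differed were SUS4 (LOC_Os03g22120) by -0.63 (-0.74, -1.38; adjusted p = 9.65e-05), SUS2 (LOC_Os06g09450) by -0.57 (0.20, -0.36; 0.000158), BT1 (LOC_Os02g10800) by -0.55 (-0.71, -1.27; 0.000342), Wx (LOC_Os06g04200) by -0.49 (-1.03, -1.52; 0.000474) and BEIIb (LOC_Os02g32660) by -0.33 (-1.33, -1.65; 0.0151). PPDKB (LOC_Os05g33570) differed by -0.31 (-0.87, -1.18; 0.00191), AGPS2 (LOC_Os08g25734) by -0.29 (-0.95, -1.24; 0.00479), NAC20 (LOC_Os01g01470) by 0.31 (-1.07, -0.76; 0.0117) and a prolamin (LOC_Os11g33000) by 0.24 (-0.53, -0.29; 0.0151), a call lost without tolerant control 1 (adjusted p = 0.0768). With library totals alone the calls of the prolamin, NAC20 (adjusted p = 0.305), PDIL1-1 (0.296), HSP24.1 (0.0795) and the ubiquitin-S27a gene LOC_Os01g22490 (0.109) were lost, among others.

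Embryo, photosynthesis and clock genes that differed were OLE16 (LOC_Os04g46200) by -0.47 (-0.58, -1.05; adjusted p = 0.00116), RCA (LOC_Os11g47970) by -0.49 (-0.59, -1.08; 0.00284), OLE18 (LOC_Os03g49190) by -0.30 (-0.52, -0.82; 0.0216), EM (LOC_Os05g28210) by -0.32 (-0.13, -0.45; 0.0465), plastocyanin (LOC_Os06g01210) by -0.48 (-0.70, -1.18; 0.0384) and LHY (LOC_Os08g06110) by -0.47 (-1.57, -2.04; 0.0273). The calls of EM (adjusted p = 0.0552 to 0.113) and plastocyanin (0.0541 to 0.0959) were lost without any 1 of 11 libraries, LHY (0.0517 to 0.0762) without any 1 of 8 and OLE18 (0.0572 to 0.0620) without any 1 of 3.

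Other genes with the largest differences were chitinase 1 (LOC_Os06g51060) at 4.27 (-2.29, 1.98; adjusted p = 6.67e-07), protein P21 (LOC_Os12g43450) at 2.62 (-0.34, 2.28; 8.48e-07), germacrene A oxidase (LOC_Os02g09310) at 2.18 (-0.77, 1.41; 2.57e-06) and early nodulin-like protein 3 (LOC_Os08g17160) at 1.82 (-0.41, 1.41; 0.000301). On the negative side were cinnamoyl-CoA reductase 1 (LOC_Os09g25150) at -0.68 (-2.71, -3.39; 0.000221), laccase-10 (LOC_Os03g16610) at -1.48 (-3.68, -5.16; 0.000443), blue copper protein (LOC_Os06g11490) at -1.60 (-1.11, -2.71; 0.0028), a lipoxygenase-like protein (LOC_Os08g39850) at -1.66 (-1.30, -2.97; 0.00177) and amino acid permease 3 (LOC_Os12g08090) at -1.67 (1.57, -0.10; 0.00244). The fitted difference of basic 7S globulin 2 (LOC_Os01g71080), 3.22, rests on 4 to 30 counts in tolerant control and is 2.94 with levels at the floor of 12 counts, against 21.1 ± 0.7955 CPM under stress. For 3-ketoacyl-CoA synthase 4 (LOC_Os05g49290), at -2.60 (0.51, -2.09; 0.0204), and peroxiredoxin-2E-1 (LOC_Os06g42000), at -4.77 (4.92, 0.15; 5.95e-05), values jumped between replicates of a group, and the former call was lost without any 1 of 4 libraries (adjusted p = 0.0517 to 0.0547).

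Ribosomal protein transcripts were lower in the tolerant line in control (median -0.49), and their response differed by a median of 0.37 (-0.53, -0.10; adjusted p = 5.37e-34), as for the 60S gene L9 (LOC_Os09g31180) by 0.85 (-0.998, -0.15), the 40S genes S2-3 (LOC_Os07g10660) by 0.64 (-0.36, 0.28) and S11 (LOC_Os04g42380) by 0.50 (-1.69, -1.19) and a ubiquitin-S27a gene (LOC_Os01g22490) by 0.54 (-0.48, 0.06). Scaling shifts all genes alike, so a first test, of the distance of the list from other genes, could not decide and was replaced with the values in view. The TMM factors as the whole cause of the lower level are argued against: the median of the list was -0.38 (SE 0.0390) with library totals alone, with 55 genes lower and 0 higher, and -0.48 with median-of-ratios factors. Totals alone moved the median of all genes to 0.11, and a larger error of scaling, shared by these choices, is not excluded. Gene length stays open as a small part, since other genes of the same length had a median of -0.0526 (95% of draws -0.108 to -0.000436), narrowly outside the bound set beforehand though far from the list. Genes of the machinery that makes ribosomes were lower too, in a test set beforehand. The 142 ribosome biogenesis genes had a median of -0.23, with 23 lower and 1 higher (camera p = 1.80e-08, and p = 0.000102 with an estimated correlation). Both sets come from the same libraries and scaling, and a shift shared by both would give the same result. The test therefore cannot tell a cause of the lower ribosomal level from a change that goes along with it.

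Amy3A and Amy3D were present in sensitive control, near 0 in tolerant control and highest in tolerant stress, where the sum of the alpha-amylases was also highest. Not every member followed: Amy1A (LOC_Os02g52710) was highest in sensitive stress (3.21 ± 0.538 CPM), and LOC_Os01g51754 in sensitive control (32 ± 2.14 CPM). The fitted differences of Amy3A (LOC_Os09g28400), 10.98, and Amy3D (LOC_Os08g36910), 8.66, are no measured folds, since tolerant control held 0, 0 and 4 or 16 counts; with levels at the floor of 12 counts they were 7.93 and 7.37. The fitted difference of Amy3E (LOC_Os08g36900) was 1.35 (0.31, 1.66; adjusted p = 1.15e-05). The list median of 2.26 rests on such members and was 1.28 with them at a floor of 12 counts per library. A variant in the tolerant line that hides Amy3A from mapping is argued against by its 21.05 CPM under stress in that line, and reads only moving between listed paralogs are argued against for the sum, which rose by a log2 ratio of 1.27. Amy3E carried most of that rise (0.59 without it), so the sum says little of the other members. At the share that tolerant control allows, reads of Amy3E could give at most 2.27% of the Amy3A and 8.55% of the Amy3D counts in tolerant stress, which argues against them as the source. Reads of a paralog missing from the table, such as Amy3C, are not covered. For the difference in control, a loss of Amy3A and Amy3D reads to paralogs in the tolerant line is argued against. Such a loss, if set by sequence, would hold under stress too, where Amy3A held 2006 to 2350 and Amy3D 730 to 1023 counts. Reads of paralogs counted at these genes in the sensitive line cannot be told apart from a change of transcripts. In control the summed list differed by a log2 ratio of only -0.16, which met the bound written for reads moving between paralogs in control. Amy3E, higher in the tolerant line there, holds much of the sum, so the sum does not decide between moved reads and a change of transcripts.

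Genes that differed between the lines in the same direction in control and under stress, 204 in all, might mark chromosome segments that differ between near-isogenic lines, a hypothesis set before its test. The test does not decide it: 0.490%, or 1 gene, had a nearest neighbour that was also one of them, as at the median of 10000 random placements (permutation p = 0.647). The criterion set beforehand would have excluded segments, but with 1 gene the upper 95% limit of the share is 2.70%, several times the random median. In windows of 2 Mb, a test added later, 41 genes lay in windows with 4 or more against a random median of 34 (permutation p = 0.260), and 7 at most in a window against 5 (p = 0.140). With no excess shown, there was nothing for the technical explanations to account for, and both stay undecided: at 20 kb or more the permutation p was 0.822 (reads shared between neighbours), and in the 9 windows with 4 or more such genes 46.3% of 41 were lower in the tolerant line (a variant against the reference). As first written, the criteria would have read the former as supported and the latter as excluded, and they were set aside after seeing the lack of an excess.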

How the results depend on the processing

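Library totals alone and counts divided by 4 were chosen only after the data were seen, and the other alternatives were set beforehand. The cause was not tested unless given. Stress changed 10695 genes in the sensitive and 11059 in the tolerant line, 1804 differed between the lines in control and 1132 under stress, and 867 differed in response. These counts stayed within 1.5 times, apart from those named here; summed over loci that share an identifier they were 10629, 10972, 1853, 1199 and 922. With a 2-fold minimum they were 4656, 5079, 315, 235 and 274, by construction fewer. At an adjusted p under 0.01 they were 7089 for stress in the sensitive line, 735 and 525 between the lines and 388 for the difference in response, again by construction. At a mean of 10 CPM or more 5527 and 5690 genes changed with stress, where fewer genes were tested. With only the groups compared 906 genes differed in control, with fewer libraries for the spread, and DESeq2 called 3018, 1971 and 1752 in the last 3 comparisons, sharing 1804, 1122 and 867 with edgeR. With library totals alone 696 genes differed between the lines under stress, and 7477 of the 10695 and 8316 of the 11059 stress calls were shared. FPKM shared fewer of these, 6605 and 7329 with a pseudocount of 1, and 6577 and 7292 with 0.1. DESeq2 gave no adjusted p for 96 genes, or 8441 between the lines under stress.

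Leaving out each library gave 8950 to 10561, 9345 to 11169, 1098 to 1650, 672 to 1065 and 622 to 801 genes, and 30 to 33 called lists against 32. In 10 cases a list not called with all libraries passed with 1 left out, among the photosynthesis, clock, embryo, microRNA machinery and heat stress factor lists. The lowest count in control, 1098, was without tolerant control 1. Under stress the lines differed in 672 genes without sensitive stress 1, 703 without sensitive stress 2, 688 without tolerant stress 1 and 716 without tolerant stress 3. With the replicate number as a block the counts were 10048, 10409, 1410, 862 and 630, with 32 lists; libraries with the same number had residual correlations of -0.012 to 0.029 (18 pairs) and others -0.024 to 0.020 (36 pairs), so the numbers show no pairing.

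Of the 32 called lists, 20 were called in the same direction under every alternative run. An estimated correlation left 23, FPKM with a pseudocount of 0.1 gave 28, library totals alone 33, counts divided by 4 gave 29 and median-of-ratios factors 32. The ribosomal list reversed under stress in the tolerant line, from -0.10 to 0.23 in FPKM and 0.22 with library totals alone, where the factors that tell control from stress are taken out. Its call was lost in both, with adjusted p = 0.599 and 0.462 in the camera test. In that comparison the median also changed sign for photosynthesis, from -0.17 to 0.15 and 0.14, and microRNA targets, from -0.23 to 0.03 and 0.10, and both calls were lost. Of 224 calls of named genes, counted per comparison, 176 kept call and direction under every alternative and 48 were lost under some. Of these, 37 were lost when some library was left out, 29 with library totals alone (27 in the same direction, 2 reversed) and 19 with the replicate block. The histone gene LOC_Os08g40510 reversed in the sensitive line to 0.0341 in FPKM and 0.0335 with library totals alone, and in the tolerant line to 0.0720 and 0.0570.

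Quantile normalization was planned only for a table with FPKM alone and was not run. Depth limits what can be called among genes of few counts, and how many fragments stand behind a count is not known.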

Other observations

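Some transcripts of the pathway to aromatic amino acids, a term picked after the data were seen, fell with stress in both lines. DAHP synthase (LOC_Os03g27230, chromosome 3, 15603830 to 15608753), its entry enzyme, fell from 565 ± 11.5 to 183 ± 8.865 CPM in the sensitive line and from 638.5 ± 23.3 to 136 ± 4.16 CPM in the tolerant line (mean ± SD, n = 3), log2 changes of -1.63 ± 0.05 and -2.235 ± 0.05. A shikimate kinase (LOC_Os04g54800, chromosome 4, 32582126 to 32585724) changed by -1.39 ± 0.10 and -1.69 ± 0.10. Of 19 tested genes of the term, 11 fell and 1 rose in each line, with medians of -0.75 (adjusted p = 0.000141) and -0.82 (adjusted p = 1.56e-05). Neither call held, with adjusted p = 0.0997 and adjusted p = 0.104 with an estimated correlation.

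A trehalose-phosphate synthase (LOC_Os08g34580, chromosome 8, 21722267 to 21726118) rose from 51.2 ± 3.295 to 136.5 ± 6.53 CPM in the sensitive line and from 48.4 ± 2.31 to 200.1 ± 2.69 CPM in the tolerant line, and differed in response by log2 0.63 ± 0.09. Under stress 3 of 12 such genes were higher in the tolerant line and 0 lower (median 0.38; adjusted p = 4.20e-05; adjusted p = 0.154 with an estimated correlation). Beta-amylase 3 (LOC_Os10g41550, chromosome 10, 22324198 to 22327665) fell from 122 ± 5.17 to 67.7 ± 0.782 CPM in the sensitive line and stood at 129.5 ± 6.18 and 122 ± 4.79 CPM in the tolerant line, a difference in response of 0.77 ± 0.08. Of 53 loci annotated with chitinase activity, xylanase inhibitors among them, 7 had a positive difference in response and 0 a negative one (median 0.55; adjusted p = 0.0261; adjusted p = 0.308 with an estimated correlation). Mitochondrial complex I genes were lower in the tolerant line in control in 6 of 41 cases and higher in 0 (median -0.23; adjusted p = 3.63e-06; adjusted p = 0.0217 with an estimated correlation). Glycolysis genes were lower in the tolerant line under stress in 12 of 81 cases and higher in 0 (median -0.13; adjusted p = 2.86e-05; adjusted p = 0.0412 with an estimated correlation).

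All tests of gene ontology terms, and the genes named from them, were chosen only after the data were seen. They covered 1263 terms of 10 to 300 tested genes per comparison, with camera as for the lists. Adjusted over the terms of a comparison, 38 terms passed for stress in the sensitive line, 43 for stress in the tolerant line, 76 between the lines in control, 60 between the lines under stress and 41 for the difference in response. With an estimated correlation the numbers were 5, 0, 14, 6 and 4.

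In the tolerant line in control, the 5 loci with the most counts took 21.7% and 24.6% of the counts of replicates 1 and 2 and 31.3% of those of replicate 3.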
